A study of Danio rerio with 6 samples.

How the data were processed

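Whole-brain RNA of adult zebrafish was measured in 6 libraries, 3 from wild-type (WT) fish and 3 from fish homozygous for the chrna3 C246X allele. Each library was assigned to its genotype and replicate number per the labels, and no library was left out. Reads of 150 bp, sequenced as pairs, were aligned with STAR to GRCz11, per the submitters' processing notes, which state no versions. The counter, the annotation release and the scaling are not given in the sources used here.

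The deposited matrix gives 1 signal value per library for each of 23678 Ensembl genes. From the values themselves, the deposited signal is an estimated read count divided by 1 factor per library, and the factors look like median-of-ratios size factors. The low values of each library are multiples of 1 step close to 1, and 95.0% to 95.2% of values under 1000 reads are whole multiples within 0.03. The steps gave factors of 0.944 to 1.00. Deposited totals were 25655952 to 26794838 per library and recovered totals 24222343 to 26659977. The 10 most abundant genes held 6.53% to 8.15% of a library. The design had assumed counts, so its stated test for normalized values was used.

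Genes with a mean value of at least 1 were tested (23104 of 23678, with 574 below the minimum, 189 of them at 0 in every library). Values were put on the log2(value + 1) scale and fitted with limma 3.58.1 in R 4.3.3 by genotype, with a mean-variance trend and robust moderation off, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Adjusted p-values for single genes in the report come from this fit. The chrna3 level was also tested by an exact two-sided permutation test. On simulated data for C246X against WT, with 23017 genes, the fit recovered 91% of genes changed by 2-fold and 100% of those changed by 4-fold and called 0.0263% of unchanged genes. The changed genes were drawn from those without low means, and every gene was simulated independently at a dispersion of 0.02. The recovery therefore does not cover low genes, and no rate covers genes that vary more or vary together.

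The 33 gene lists were written before the data were examined: neurotransmitter systems, pathways, brain cell types and tissues next to the brain. Members were matched by current or older symbol, 16 wrongly matched genes were removed by hand, and lists needed 5 tested members. Lists were tested two-sided with camera at the preset correlation of 0.01, adjusted over the lists, then with an estimated correlation and with fry. A list member counts as higher or lower when it passed over all genes, and the count adjusted over the list alone stands beside it.

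Symbols came from a gene-name table, in which 22274 genes have a symbol and 3361 share it with another gene. Shared symbols are printed with the Ensembl identifier. Gene order and gene spans came from a table of another assembly (GRCz12tu), joined by unique current or older symbol, so no coordinates are printed and the planned bins by distance from chrna3 were replaced by neighbours in gene order. A check by place or span was void where fewer than 80% of its genes could be joined.

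The rule for named genes, set in advance, took chrna3 and all nicotinic subunits. It took the 12 largest rises, the 12 largest falls and the 6 most abundant genes among those that passed, had a mean of at least 1 CPM, an approved-style symbol and no overlap between the genotypes. It also took, from each list, the 2 members with the smallest p in each direction. Genes named outside it are marked as such, and some genes that the rule takes are not reported here.

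Alternatives were recomputed medians of ratios, upper-quartile and total-count scaling, no filter, a filter of 1 CPM in 3 libraries, limma-voom on the recovered estimates, a pseudocount of 0.1 (0.5 for lists), a replicate block, a minimum log2 change of 1, and each library left out. Total-count scaling, dropping the genes near 0 in 1 genotype and extending lists by shared symbols were added after the data were seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.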

Results

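Whole brains of adult zebrafish homozygous for C246X, a premature stop introduced by CRISPR/Cas9 into chrna3, were compared with whole brains of wild-type (WT) fish by sequencing of polyadenylated RNA. The gene chrna3 encodes the alpha3 subunit of the neuronal nicotinic acetylcholine receptor, and the series was set up to study the response of zebrafish to alcohol. The data held 3 libraries per genotype, with paired reads of 150 bp. Values were estimated reads per gene divided by 1 factor per library, and their sums lay between 25655952 and 26794838 per library. Undoing the factors gave 24222343 to 26659977 estimated reads per library, so depth was close between genotypes. The labels do not say whether the libraries came from separate fish or from pools, so p-values measure only the spread between these samples, which may be technical. Values below are given as mean ± SD over 3 libraries, and fold changes as C246X minus WT on the log2(value + 1) scale. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 in limma.

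The transcript of chrna3 itself was low and variable in both genotypes. Its values were 102, 28.1 and 55.1 in the WT libraries and 59.8, 40.7 and 57.4 in the C246X libraries. The means were 61.6 ± 37.1 in WT and 52.7 ± 10.4 in C246X, with a log2 fold change of −0.06 (95% interval −1.04 to 0.93, adjusted p = 0.94). The exact two-sided permutation p was 1, where 3 libraries against 3 cannot go below 0.1. A premature stop need not lower the transcript, so this level does not check the genotype labels. Leaving out WT replicate 1 or C246X replicate 2 turned the sign, to 0.39 and 0.11.

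Among the nicotinic receptor subunits, 1 of 25 tested genes rose and 2 fell, and the list as a whole did not pass (camera, adjusted p = 0.265). The epsilon subunit gene CHRNE, known from the neuromuscular junction, rose from 29.2 ± 7.38 to 102 ± 13.8 (log2 fold change 1.79, adjusted p = 0.00203). A CHRNA2 copy (ENSDARG00000006602) fell from 96.9 ± 22 to 49.7 ± 10.2, and a CHRNB1 copy (ENSDARG00000069660) fell from 19.8 ± 3.24 to 8.49 ± 0.502. Another CHRNA2 copy (ENSDARG00000057025) had 200 ± 46.7 in WT and 286 ± 50.1 in C246X and did not pass. Nor did another CHRNB1 copy (ENSDARG00000022532), with 4.38 ± 2.02 in WT and 1.02 ± 1.03 in C246X. The subunits that share receptors or a gene cluster with alpha3 did not pass. CHRNA5 had means of 389 ± 20.6 in WT and 380.0 ± 37.9 in C246X, CHRNB4 of 60.3 ± 7.06 in WT and 86.3 ± 8.37 in C246X and CHRNB2 of 2071 ± 39.4 in WT and 2153 ± 61.8 in C246X. Adjusted over the list alone, 1 subunit was higher and 0 were lower. The subunits that fell numbered 1 without WT replicate 1 or C246X replicate 2 or at 1 CPM, and 0 without WT replicates 2 or 3 or C246X replicates 1 or 3, and those that rose 2 without WT replicate 1. Other cholinergic genes passed as a list (camera, adjusted p = 0.0374; 0.00436 to 0.36 over alternatives, the highest with an estimated correlation), with 4 of 13 higher and 0 lower (5 and 1 when adjusted over the list alone). LYPD6B, of a family of proteins that bind nicotinic receptors, rose from 11.9 ± 3.51 to 170.4 ± 24.4, and a copy of the muscarinic receptor gene CHRM2 (ENSDARG00000098612) rose from 183 ± 69.4 to 670.1 ± 29.3. The acetylcholinesterase gene ACHE and a copy of the vesicular transporter gene SLC18A3 (ENSDARG00000006356), named after their values were seen, rose by 0.35 and 0.81. That list no longer passed without C246X replicate 3 (adjusted p = 0.0736). Its higher members numbered 2 without WT replicate 3 or C246X replicates 1 or 3, and its lower members 1 without C246X replicate 3.

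Across the transcriptome, 5207 of 23104 tested genes (22.5%) differed between the genotypes, 2569 higher and 2638 lower in C246X brains. Of these, 1842 differed by at least 1 on the log2 scale, 609 of them higher and 1233 lower. The libraries of the genotypes did not overlap in 9575 genes (41.4%), where chance gives 10% for 3 against 3. The first principal component held 56.9% of the variance and separated the genotypes. The second held 13.9% and spread the WT libraries (66.7, −47.3 and −16.4) more widely than the C246X libraries (8.90, −10.1 and −1.73). Without C246X replicates 1, 2 and 3 in turn, 2986, 3252 and 3259 genes differed.

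Several of the steepest falls went from high WT levels to almost nothing. The gene taco1, a translational activator of a mitochondrial oxidase subunit, had 627 ± 60.5 in WT and was listed at 0 in all 3 C246X libraries, as was the galectin gene lgals1l1 against 104 ± 26.1 in WT. The MHC class II gene mhc2dab fell from 1601 ± 642 to 3.07 ± 1.06, an SMC1A cohesin copy (ENSDARG00000055754) from 1314 ± 316 to 3.4 ± 1.56, and a FABP7 copy (ENSDARG00000034650), which encodes a fatty-acid-binding protein of radial glia, from 704 ± 161 to 2.05 ± 1.8. The centriole gene cpap fell from 8767 ± 523 to 41.7 ± 11.1, the protocadherin gene pcdh1g18 from 469 ± 31.4 to 2.61 ± 2.7 and a copy of the globin gene HBE1 (ENSDARG00000097238) from 1783 ± 1072 to 11.5 ± 9.3. Also among the 12 largest falls were znf977, ifit8, a GGACT copy (ENSDARG00000038248) and the retroviral gene erv, whose C246X values spread widely (358 ± 596).

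Among the 12 largest rises, the zinc-finger gene znf1179 rose from 94.3 ± 11.2 to 6927 ± 121 (log2 fold change 6.19, SE 0.094, adjusted p = 4.39e-08), and a MCF2L copy (ENSDARG00000076480), a guanine-nucleotide exchange factor, from 149 ± 16.9 to 3409.7 ± 155. The protocadherin gene pcdh2ac rose from 8.46 ± 5.06 to 731 ± 479.6, the kinase gene pak6b from 1.38 ± 1.19 to 72.5 ± 17.7 and a copy of the mitochondrial deubiquitinase gene USP30 (ENSDARG00000104175) from 0.685 ± 0.594 to 53 ± 2.32. HOXC8 and HOXB9, transcription factors of trunk identity, rose from 8.13 ± 7.97 to 112 ± 17.1 and from 3.72 ± 3.02 to 58.2 ± 32. The others of these 12 were znfl1l, znf1181, LYPD6B, oclna and a gene of a long intergenic noncoding RNA (ENSDARG00000094560). In all, 104 genes were at or under 3 in every library of 1 genotype while averaging at least 20 in the other, 78 of them near 0 in C246X and 26 in WT, and 84 of these passed. Protocadherin, zinc-finger, MHC and globin genes have close copies, so reads split between copies make single values in these families uncertain.

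Genes of the interferon response, the antiviral programme, fell together. Of 36 tested members 30 fell and 0 rose, with a median log2 fold change of −2.71 (camera, adjusted p = 4.69e-20; 8.64e-23 to 0.26 over alternatives, the highest with an estimated correlation). Adjusted over the list alone, 31 were lower and 1 was higher. The gene isg15, which encodes a ubiquitin-like protein, fell from 2346 ± 169.6 to 57.6 ± 16.4 (log2 fold change −5.36, SE 0.18, adjusted p = 1.84e-06). None of the 4 members with positive fold changes passed over all genes, among them SAMHD1 with 169 ± 8.83 in WT and 205 ± 9.04 in C246X and parp9 with 404 ± 22.9 in WT and 414 ± 28.6 in C246X.

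Immune cell markers were lower in the same libraries. Of 42 microglia and macrophage markers 29 fell and 1 rose (median −1.15; camera, adjusted p = 3.18e-12; 1.44e-14 to 0.36 over alternatives, the highest with an estimated correlation), and 30 and 1 passed when adjusted over the list alone. The granulin gene grna fell from 1073 ± 23.3 to 306 ± 53.4 and an MPEG1 copy (ENSDARG00000055290), a macrophage perforin gene, from 544 ± 47 to 222 ± 32.6. The exception was the phagocyte oxidase gene cybb, which rose from 431 ± 6.82 to 803 ± 40.3. Of 28 lymphocyte and neutrophil markers 10 fell (14 adjusted over the list alone) and 0 rose (median −1.28; camera, adjusted p = 0.000967; 8.39e-05 to 0.449 over alternatives, the highest with an estimated correlation), the interleukin receptor gene il6r from 188 ± 40.1 to 61.7 ± 16.9. This count was 6 without C246X replicate 1, and 4 without WT replicate 3.

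In the MHC and antigen processing list, 15 of 31 members fell and 1 rose (median −0.79; camera, adjusted p = 8.27e-05; 7.45e-07 to 0.36 over alternatives, the highest with an estimated correlation), with 16 lower and 1 higher when adjusted over the list alone. The class II gene mhc2daa fell from 1979 ± 502 to 308 ± 59.2, and tapbp.2, a chaperone gene of peptide loading, rose from 94.7 ± 26.1 to 197 ± 24.7. The members that rose numbered 2 without C246X replicates 1 or 3.

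**Figure D1:**
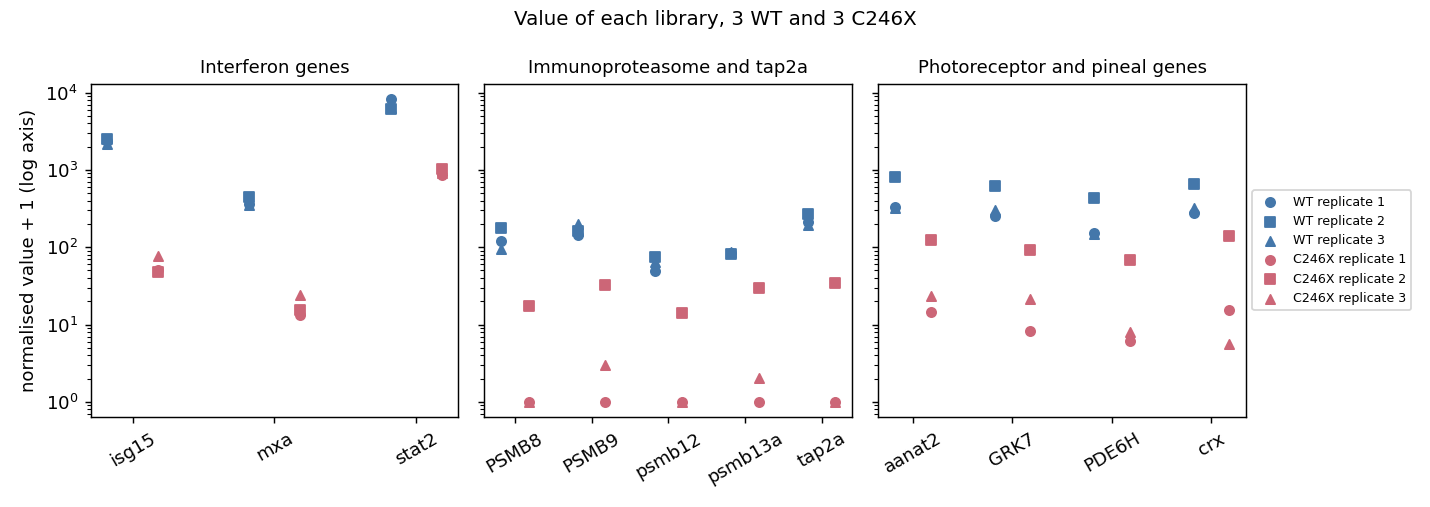
Each symbol is the value of 1 library plus 1, on a log axis, for the genes named under each panel, with WT in blue, C246X in red and the replicate number as the symbol's shape. The interferon genes shown, not all of them taken by the naming rule, sit apart by genotype in every library. The 5 antigen processing genes and the photoreceptor and pineal genes shown spread widely among the C246X libraries, with C246X replicate 2 the highest of its genotype in their panels (tap2a at 33.6 against 0 and 0).

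Photoreceptor and pineal genes were also lower in C246X brains, with a wide spread between libraries of 1 genotype. Of 48 members 24 fell and 0 rose (median −2.64; camera, adjusted p = 4.33e-07; 1.11e-16 to 0.455 over alternatives, the highest with an estimated correlation), and 29 were lower when adjusted over the list alone. The melatonin synthesis gene aanat2 fell from 486 ± 275 to 52.3 ± 59.9 and a copy of the opsin kinase gene GRK7 (ENSDARG00000055534) from 394 ± 204 to 39.7 ± 45.5. Only 2 members fell without WT replicate 2 or without C246X replicate 1, 4 without C246X replicate 3 and 5 without WT replicate 3, and by fry the list did not pass (adjusted p = 0.0941). Lens and retina markers did not pass in 1 direction by camera (camera, adjusted p = 0.237) but passed as lower by fry (adjusted p = 0.034; range over alternatives 0.034 to 0.452), with 4 of 21 lower (4 adjusted over the list alone), among them the small heat shock gene CRYAB (ENSDARG00000101380), from 152 ± 39.4 to 23.4 ± 0.281. The others were the retinoid-binding genes rlbp1a, rlbp1b and rbp3, of which rlbp1b and rbp3 were named after their values were seen. The lens and retina markers that fell numbered 2 without WT replicates 1 or 3, and 1 without WT replicate 2 or C246X replicates 1 or 3.

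Circadian clock genes changed in both directions. The hour of sampling is not stated for either genotype, and levels of clock genes depend on it. Neither the values of other lists, such as the pineal, immediate early and glucocorticoid genes, nor those of the clock genes separate genotype from hour. Of 35 members 10 rose and 14 fell, 11 and 15 when adjusted over the list alone, and the list did not pass in 1 direction by camera (camera, adjusted p = 0.0786). It passed as lower by fry (adjusted p = 0.0265), with lists extended by shared symbols (0.0389), without WT replicate 3 (0.0434) and without C246X replicate 1 (0.0404), with a range of 0.0265 to 0.551 over alternatives. The rotation test for change in either direction gave an adjusted p of 2.89e-05, but 30 of the 33 lists passed that test, so it does not mark out clock genes. The repressor genes ciarta and PER1 (ENSDARG00000056885) fell from 2163 ± 54.5 to 858 ± 42.7 and from 1603 ± 25.2 to 804 ± 49.9. The orphan receptor genes rorcb and rorca rose from 365 ± 19.6 to 658 ± 41.9 and from 409 ± 14.2 to 671 ± 33.1. Chosen after their values were seen, the activator genes CLOCK (ENSDARG00000011703), npas2 and a BMAL1 copy (ENSDARG00000006791) rose by 0.79, 0.75 and 0.59, and the repressor genes NR1D1, PER2 and PER3 had fold changes of −1.15, −0.83 and −0.83.

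**Figure D2:**
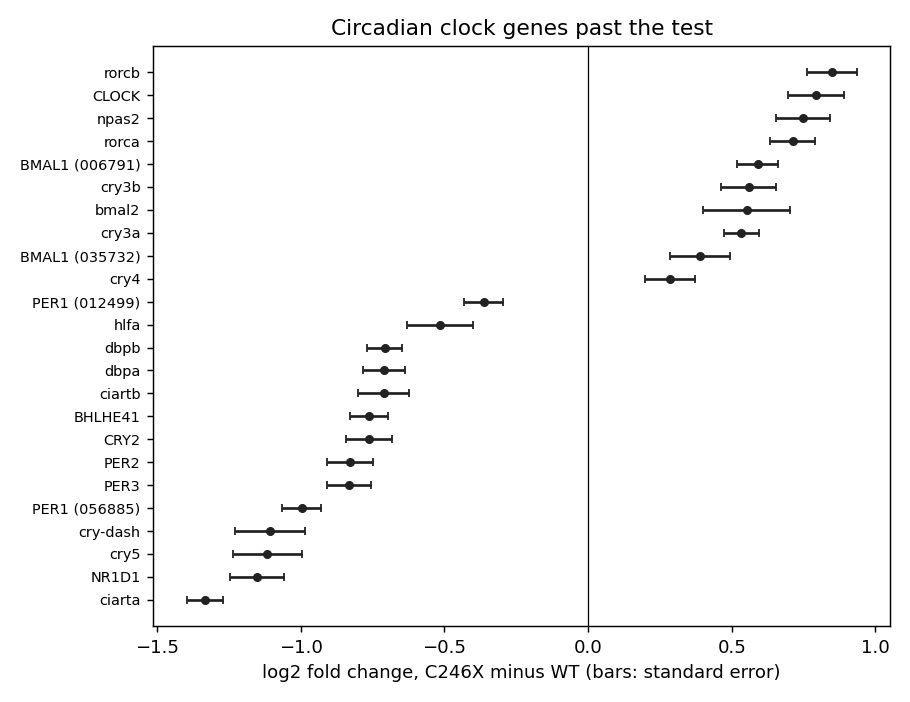
The log2 fold change (C246X minus WT, points) and its standard error (bars) are shown for the 24 clock genes that passed. The CLOCK, BMAL1, npas2 and ror genes lie above 0 and the PER, dbp, ciart and NR1D1 genes below, with ciarta lowest at −1.33.

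Immediate early genes, which respond to neuronal activity, were lower. Of 40 members 21 fell and 1 rose (median −0.60; camera, adjusted p = 2.02e-08; 4.28e-09 to 0.36 over alternatives, the highest with an estimated correlation), and 24 and 1 passed when adjusted over the list alone. A FOS copy (ENSDARG00000031683) fell from 1236 ± 139 to 281 ± 50.3 and an NPAS4 copy (ENSDARG00000055752) from 4186 ± 804 to 1309 ± 72, while csrnp1a rose from 147 ± 35.7 to 236 ± 42.8. The members that rose numbered 2 without WT replicate 1, and 0 without WT replicates 2 or 3 or C246X replicates 1, 2 or 3, with no filter or with a pseudocount of 0.1.

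The lists of voltage-gated channel, glutamate, GABA and neuropeptide genes passed as higher by camera, with medians of 0.33 or less. Single members moved further, and those that passed over all genes went both ways only among GABA and neuropeptide genes. Of 44 voltage-gated channel genes 20 rose and 0 fell (median 0.33; camera, adjusted p = 3.12e-09; 5.67e-11 to 0.36 over alternatives, the highest with an estimated correlation), and 21 were higher when adjusted over the list alone. The sodium channel gene scn1lab rose from 2653 ± 235 to 4954 ± 217 and the potassium channel gene KCNQ3 from 348 ± 33.2 to 656 ± 47.2. Among glutamate genes 11 of 32 rose and 0 fell (median 0.20; camera, adjusted p = 0.000343; 4.66e-05 to 0.36 over alternatives, the highest with an estimated correlation), 13 and 2 when adjusted over the list alone, with the receptor gene GRM3 going from 606 ± 25.8 to 926 ± 27.7. Among GABA genes 7 of 31 rose and 2 fell (median 0.17; camera, adjusted p = 0.00662; 0.00201 to 0.449 over alternatives, the highest with an estimated correlation), and the counts were the same when adjusted over the list alone. The receptor subunit gene gabra3 rose from 54.5 ± 6.07 to 207 ± 28.4, and a copy of the GABA synthesis gene GAD1 (ENSDARG00000027419) fell from 62066 ± 26206 to 23348 ± 1096. The other member that fell was a GABRR1 copy (ENSDARG00000043902), while another GABRR1 copy (ENSDARG00000098081) rose from 55.0 ± 5.46 to 181 ± 5.52. The GABA genes that rose numbered 4 without WT replicate 3 or under total-count scaling and 2 without C246X replicate 1 or 3, and the glutamate genes 7 without C246X replicate 1. The glutamate genes that fell numbered 1 without WT replicates 1 or 2 or C246X replicate 2. Neuropeptide and opioid receptor genes had 5 of 53 higher and 1 lower (median 0.14; camera, adjusted p = 0.0374; 0.00942 to 0.455 over alternatives, the highest with an estimated correlation; 3 and 1 adjusted over the list alone). The feeding peptide genes agrp and pmchl rose from 5.38 ± 4.15 to 40.7 ± 11.3 and from 339 ± 75.4 to 681 ± 76.2, and avp, the vasotocin gene, fell from 302 ± 32.8 to 160.0 ± 43.2. The others that rose were tac1 and, named after their values were seen, cart4 and kiss2. The neuropeptide list no longer passed without WT replicate 2 (adjusted p = 0.17) or without C246X replicate 3 (0.0736), nor by fry (adjusted p = 0.108), and at 1 CPM it missed the threshold (0.0576). Its higher members numbered 3 without WT replicates 2 or 3 or C246X replicates 2 or 3. Neuron markers did not move as a list (6 higher and 3 lower of 41, the same adjusted over the list alone; median 0.02; camera, adjusted p = 0.556), and the lower ones were tubb5, gap43 and, named after its values were seen, sncb. The neuron markers that fell numbered 6 without WT replicate 2, and 1 without C246X replicate 1, and those that rose 3 without C246X replicates 2 or 3.

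The monoamine lists did not pass by camera. Of 23 dopamine and noradrenaline genes 2 rose and 3 fell (camera, adjusted p = 0.0915; 4 and 3 adjusted over the list alone), and the synthesis gene TH rose from 215 ± 30.4 to 394 ± 49.3. DDC and, named after its values were seen, SLC6A2 fell. The dopamine and noradrenaline list passed with lists extended by shared symbols (adjusted p = 0.0427) and without WT replicate 1 (0.0448), with a range of 0.0427 to 0.562 over alternatives. Its members that rose numbered 5 without WT replicate 1, and 1 without C246X replicates 1 or 3, and those that fell 1 without C246X replicates 1 or 3. Of 21 serotonin genes 0 rose and 2 fell (camera, adjusted p = 0.583; the same adjusted over the list alone), and the synthesis gene TPH2 fell from 715 ± 149 to 338 ± 120.0, as did the receptor gene HTR2B from 26.9 ± 20.5 to 2.72 ± 2.12. The serotonin genes that fell numbered 1 without WT replicates 2 or 3, at 1 CPM or in limma-voom, and 0 without C246X replicates 1 or 3, and those that rose 1 without WT replicate 1. Habenula and interpeduncular markers, a circuit known in mammals for alpha3-containing receptors, had 3 higher and 1 lower of 15 (camera, adjusted p = 0.271; 4 and 1 adjusted over the list alone), with tac1 going from 925 ± 221 to 1314 ± 17.8. KCTD8 and, named after its values were seen, a NPTX2 copy (ENSDARG00000037794) also rose, and a potassium channel tetramerization gene (ENSDARG00000053542) fell. By fry the habenula list passed as higher (adjusted p = 0.0193; range over alternatives 0.0193 to 0.455). Its members that rose numbered 1 without WT replicate 3 or C246X replicate 3, and 0 without C246X replicates 1 or 2, and those that fell 0 without WT replicate 2 or C246X replicates 1, 2 or 3 or with a pseudocount of 0.1. Alcohol and aldehyde metabolism genes had 1 higher and 4 lower of 31 (camera, adjusted p = 0.22; 0 and 2 adjusted over the list alone), and ALDH4A1 fell from 1389.8 ± 31 to 1080.3 ± 18.4. ALDH1A3 rose, ALDH1L1 fell, and so did ALDH1A2 and ALDH18A1, named after their values were seen. This list passed as lower by fry (adjusted p = 0.0377; range over alternatives 0.0377 to 0.449). The alcohol genes that rose numbered 0 without WT replicates 1 or 2 or C246X replicates 1, 2 or 3, and those that fell 2 without C246X replicates 1 or 3.

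**Figure D3:**
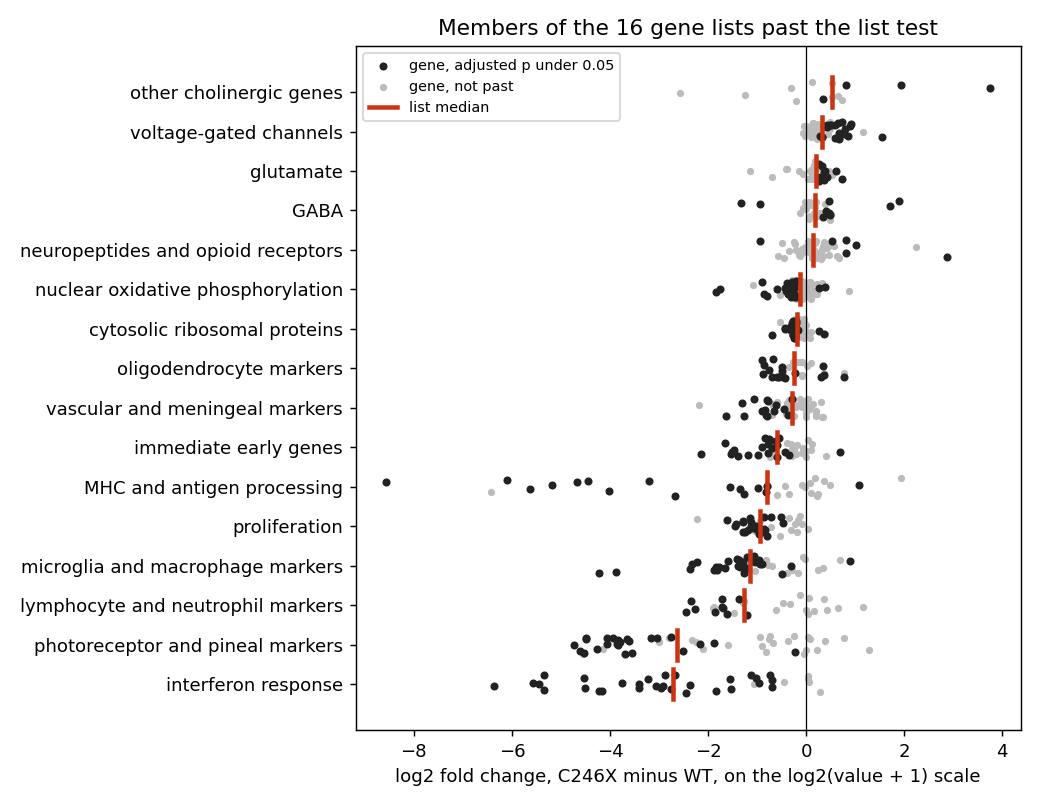
Each point is the log2 fold change (C246X minus WT) of 1 member of the 16 gene lists that passed the list test, black where the gene passed and grey where it did not, and the red line is the list median. The list medians run from −2.71 for interferon genes to 0.53 for cholinergic genes.

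Genes of dividing cells were lower: 26 of 39 proliferation genes fell and 0 rose (median −0.93; camera, adjusted p = 9.02e-11; 2.89e-13 to 0.449 over alternatives, the highest with an estimated correlation; 28 lower adjusted over the list alone), the replication gene MCM4 from 397 ± 59.9 to 182 ± 28.7. Without C246X replicate 1 the count was 16. Oligodendrocyte markers had 13 of 28 lower and 4 higher (median −0.25; camera, adjusted p = 0.00446; 0.000592 to 0.452 over alternatives, the highest with an estimated correlation; 14 and 4 adjusted over the list alone), with the myelin gene cldnk going from 6186 ± 386 to 3634 ± 68.8. The higher ones were MYRF, CSPG4 and, named after their values were seen, erbb3b and OLIG2. The lower oligodendrocyte markers numbered 8 without C246X replicate 2, and 7 without C246X replicate 1, and the higher ones 2 without WT replicate 2, and 1 without C246X replicates 1, 2 or 3. Vascular and meningeal markers had 15 of 50 lower and 0 higher (median −0.29; camera, adjusted p = 0.000374; 0.000122 to 0.36 over alternatives, the highest with an estimated correlation; 17 lower adjusted over the list alone), such as the collagen gene col6a1, from 524 ± 42.5 to 220.0 ± 35.4. The higher vascular markers numbered 1 without WT replicates 1 or 3 or C246X replicate 1. Radial glia and astrocyte markers did not pass by camera (2 higher and 6 lower of 23, the same adjusted over the list alone; camera, adjusted p = 0.0915), and the Notch target her4.1 rose from 337 ± 81.9 to 662 ± 58.6 and NOTCH3 from 4339.7 ± 371 to 5176 ± 155. The FABP7 copy described above fell, as did MSI1, a gene of neural progenitors, from 1570.0 ± 100.3 to 972 ± 58.3. The radial glia list passed as lower by fry (adjusted p = 0.0152) and without WT replicate 3 (0.0243), with a range of 0.0152 to 0.449 over alternatives. Its lower members numbered 3 without C246X replicate 1, and its higher members 1 without WT replicates 1 or 3 or C246X replicates 1, 2 or 3, under total-count scaling or in limma-voom.

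Ribosomal protein genes were slightly lower, 26 of 83 past the test and 2 higher (median −0.19; camera, adjusted p = 1.88e-08; 9.08e-12 to 0.491 over alternatives, the highest with an estimated correlation; 32 and 2 adjusted over the list alone). RPLP1 and RPL21 rose. The lower ribosomal genes numbered 8 without WT replicate 3, 6 without C246X replicate 1, and 5 without C246X replicate 2, and the higher ones 1 without WT replicates 1 or 2 or C246X replicates 2 or 3. Nuclear oxidative phosphorylation genes had 22 of 107 lower and 2 higher (median −0.12; camera, adjusted p = 0.000185; 1.45e-06 to 0.551 over alternatives, the highest with an estimated correlation; the same adjusted over the list alone), the complex I gene NDUFB2 from 2088 ± 91.7 to 622 ± 25.3. SDHA and uqcrc2a rose. The median of the oxidative phosphorylation members with a gene span (83.2% of them), −0.11, lay inside the range of lists matched on span (−0.16 to 0.0092, percentile 20.9), and that of the ribosomal members, −0.18, at its edge (−0.18 to 0.0057, percentile 2.48), a test chosen after the values were seen. The lower oxidative phosphorylation genes numbered 14 without C246X replicate 1, 13 without WT replicate 1, 12 without C246X replicate 3, and 8 without C246X replicate 2. The higher oxidative phosphorylation genes numbered 4 without WT replicate 1, 1 without WT replicates 2 or 3 or C246X replicate 3, and 0 without C246X replicate 1. By fry neither list passed (adjusted p = 0.0734 and 0.0805). Among the 6 most abundant genes that passed, malat1, a nuclear noncoding RNA, rose by 0.38, the pump gene atp1a3a by 0.41 and CLSTN1 by 0.28, while the myelin genes mbpa and plp1b and a copy of the creatine kinase gene CKB (ENSDARG00000043257) had fold changes of −0.44, −0.86 and −0.24.

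The remaining lists did not pass by camera. Heat shock and ER chaperone genes came closest (camera, adjusted p = 0.0554), with 10 of 40 lower and 5 higher (11 and 5 adjusted over the list alone), the chaperone gene HSPA5 from 10249.6 ± 62.3 to 6955 ± 276. Those that rose were hsf1, dnajb1a and, named after their values were seen, HSPE1, HSPD1 and dnaja1, and they numbered 3 under total-count scaling or in limma-voom, and 1 without WT replicates 2 or 3 or C246X replicates 1, 2 or 3. This list passed as lower by fry (adjusted p = 0.00874), under total-count scaling (0.0367), at 1 CPM (0.0487), and without WT replicate 2 (0.0472), WT replicate 3 (0.0342) or C246X replicate 1 (0.0478), with a range of 0.00874 to 0.36 over alternatives. Glucocorticoid-responsive genes had 2 higher and 5 lower of 20 (3 and 8 adjusted over the list alone; camera, adjusted p = 0.153). NR3C2 and ZBTB16 rose, and 2 PER1 copies (ENSDARG00000056885 and ENSDARG00000012499) fell, as did CEBPB, a PDK2 copy (ENSDARG00000059054) and tsc22d3, named after their values were seen. The glucocorticoid list passed without C246X replicate 1 (adjusted p = 0.0314; range over alternatives 0.0314 to 0.491). Its members that rose numbered 1 without WT replicates 2 or 3, and 0 without C246X replicates 1 or 2, and those that fell 3 without WT replicate 1, and 2 without C246X replicate 3. Nonsense-mediated decay genes had 3 higher and 2 lower of 21, the same adjusted over the list alone (camera, adjusted p = 0.488), with the kinase gene SMG1 going from 4912 ± 329 to 7094 ± 91.3. NBAS, named after its values were seen, also rose, while ETF1 and SMG9 fell. The decay genes that rose numbered 5 without WT replicate 2, and those that fell 1 without WT replicates 2 or 3 or C246X replicates 1 or 3, and 0 without C246X replicate 2. Cholesterol synthesis genes had 1 higher and 2 lower of 25 (0 and 1 adjusted over the list alone; camera, adjusted p = 0.783). SREBF1 rose from 1216 ± 279 to 1739.5 ± 119.9, and STARD4 fell from 487 ± 14.3 to 405 ± 12.8. The cholesterol genes that rose numbered 0 without WT replicate 1 or C246X replicates 2 or 3, and those that fell 1 without WT replicates 1, 2 or 3 or C246X replicates 1, 2 or 3. The median and mean differed in sign for serotonin genes (0.12 and −0.01) and for muscle and skin markers (−0.02 and 0.19). None of 13 mitochondrially encoded genes passed, also adjusted over the list alone (camera, adjusted p = 0.49), while 1 lay at an unadjusted p under 0.05 in limma, 1 rose without WT replicate 1 and 1 fell without WT replicate 2. Among tissues next to the brain, pituitary markers had 1 higher and 1 lower of 18, PCSK1 and LHX4 (camera, adjusted p = 0.186; the same adjusted over the list alone), erythrocyte markers 4 higher and 0 lower of 20 (camera, adjusted p = 0.271; the same adjusted over the list alone), and muscle and skin markers 1 higher and 0 lower of 40 (camera, adjusted p = 0.67; 0 adjusted over the list alone). The higher erythrocyte markers were hemgn, si:ch211-250g4.3 and, named after their values were seen, znfl2a and CREG1, and the higher skin marker was krt5. Only 19 of the 36 written erythrocyte symbols were matched, and the HBE1 copy that fell, described above, was not among the tested members. The erythrocyte markers that rose numbered 2 without WT replicate 1 or at 1 CPM, 1 without WT replicate 2 or C246X replicate 1 or in limma-voom, and 0 without WT replicate 3 or C246X replicates 2 or 3, and 1 fell without WT replicate 2. The muscle and skin markers that rose numbered 0 without WT replicate 3 or C246X replicates 2 or 3, under upper-quartile scaling, under total-count scaling, in limma-voom or with a pseudocount of 0.1, and 1 fell without WT replicate 2. The lower pituitary markers numbered 0 without C246X replicates 1 or 3. In total 16 of 33 lists passed, 11 lower and 5 higher, and none passed with an estimated correlation, where the smallest adjusted p was 0.26 and 1 list lay at an unadjusted p under 0.05. The rotation test fry, which asks whether members move on balance one way, passed 18 lists, among them the alcohol, circadian, habenula, heat shock, lens and radial glia lists that camera did not pass.

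Whether changed genes gather on the chromosome of chrna3 was asked because an edited line carries a linked haplotype. On that chromosome 105 of 506 placed genes (20.8%) had changed, against 3359 of 14970 (22.4%) elsewhere, an odds ratio of 0.905 (95% interval 0.721 to 1.13, two-sided Fisher's exact p = 0.386). Over all 25 chromosomes the share ran from 18.1% to 29.1%. By the same Fisher's exact test 3 chromosomes, that of chrna3 not among them, passed at an adjusted p under 0.05, each with a larger share than elsewhere. Only 15476 of the 23104 tested genes (67.0%) could be placed, under the 80% set for such a check, so these comparisons are void as tests. Among the 19 placed genes nearest to chrna3 in gene order, 3 had changed (exact binomial 95% interval 3.38% to 39.6%).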

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

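All alternatives but total-count scaling, dropping the genes near 0 in 1 genotype and extending lists by shared symbols were fixed in advance; these 3 were chosen after seeing the data. The planned DESeq2 Wald test was not run, since the values are not counts. The count of changed genes (5207) stayed between 4819 and 5223 under other scalings, filters, pseudocounts and limma-voom. It was 2986 to 4836 with 1 library left out (1401 to 2452 higher, 1585 to 2384 lower), with fewer samples by construction, and 1842 (609 higher, 1233 lower) at a log2 change of at least 1. With the replicate block it was 4764, of which 4403 were among the calls without it, and no list test changed side. Counts in lists moved by over 1.5 times under it for nicotinic subunits (3 higher, 0 lower), cholesterol synthesis (3, 1), muscle and skin (3, 1), erythrocytes (2 higher), heat shock (3 higher), and glutamate (1 lower), habenula (2 lower) and neuropeptide genes (2 lower). Deviations of each gene from its genotype mean correlated at 0.0734, 0.0475 and 0.0554 between same-numbered libraries, too low for the numbers to pair the libraries. The deviations of each library correlated best with those of its own number, a hint from the data and not the design. The chrna3 fold change ran from −0.52 to 0.39 with 1 library left out (0.39 without WT replicate 1, 0.11 without C246X replicate 2). The odds ratio of the chrna3 chromosome, 0.848 to 0.999 with 1 library left out, was 0.636 at a log2 change of at least 1 (unadjusted Fisher's exact p = 0.0285). That is a smaller share than elsewhere among placed genes. The comparison is void as a test here too, with too few genes placed, and a cause was not tested. Lists past the test numbered 16, 0 with an estimated correlation, 18 by fry and 14 to 19 with 1 library left out. At 1 CPM the neuropeptide list did not pass (adjusted p = 0.0576). Of the single-gene results for named genes other than chrna3, under the alternatives 1821 kept direction and side of the threshold, 265 kept direction only and 4 turned. The 574 genes with a mean under 1 were not tested. Direction turned, always without passing, for cholesterol synthesis (adjusted p 0.896 by fry, 0.133 to 0.837 with 1 library left out), muscle and skin markers (0.956 at 1 CPM, 0.0952 to 0.937 with 1 left out), and, with 1 left out, mitochondrially encoded genes (0.0524 to 0.708) and neuron markers (0.12 to 0.896). With 1 library left out, the log2 fold change of CHRNA5 ran from −0.12 to 0.016 and that of parp9 from −0.011 to 0.093.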

Other observations

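Every test in this part except those on regrouped libraries, the odds ratio of the chrna3 chromosome, copies of a symbol and any next neighbour of the genes near 0 was chosen only after the result was seen.

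Hox genes, which set position along the body axis, were examined after HOXC8 and HOXB9 appeared among the largest rises. Of 31 tested Hox genes 28 had positive fold changes and 5 rose: HOXB9, HOXC9, HOXC8, hoxa9a and hoxb10a. None fell. The mean log2 value of Hox genes was 5.48, 2.52 and 5.36 in the WT libraries and 6.09, 5.87 and 6.22 in the C246X libraries, so WT replicate 2 stood apart. Among other genes 11.1% rose, and no difference in that share was found for Hox genes (odds ratio 1.54, 95% interval 0.461 to 4.08, two-sided Fisher's exact p = 0.384). That share counts only genes that passed, which the distant WT replicate 2 made harder, so it does not address a shift of the Hox genes as a set. Their median log2 fold change was 1.60, against −0.0077 for all tested genes. The lowest C246X library lay above the highest WT library in mean log2 value (5.87 against 5.48). The immunoproteasome and transporter genes PSMB8, PSMB9, psmb12, psmb13a and tap2a lay between 0 and 2.01 in C246X replicates 1 and 3 and between 13.2 and 33.6 in C246X replicate 2, against 48.8 to 269 in WT. The mean log2 value of photoreceptor and pineal genes was 6.39, 7.52 and 6.76 in WT and 3.85, 6.29 and 3.65 in C246X libraries.

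Regrouping the libraries gave too few splits for a share under 0.05: the real split called 5207 genes and the highest other 0, and the real one was 1 of 10. Of all changed genes, 64.5% (3359 of 5207, exact binomial 95% interval 63.2% to 65.8%) were placed on other chromosomes than that of chrna3. Linkage to the edited locus thus cannot be the whole cause through effects on that chromosome alone. With 506 of 15476 placed genes on it, this outcome was nearly given. The place of genes cannot address a linked variant that changes genes elsewhere. Whether the chrna3 chromosome holds a local excess was not decided (odds ratio 0.905, 95% interval 0.721 to 1.13, Fisher's exact p = 0.386), with 67.0% of tested genes placed.

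The lower interferon genes were weighed against fewer immune cells, alleles and other differences between the fish. Interferon members in no immune cell list lay lower than microglia and macrophage markers (median difference −1.56 on the log2 scale, 95% bootstrap interval over genes −2.15 to −0.25). They also lay lower than lymphocyte and neutrophil markers (−1.44, −2.58 to −0.13). An equal fall of all genes of these cells would not give that difference. But the markers did not fall alike: of 42 microglia and macrophage markers 29 fell, while cybb rose from 431 ± 6.82 to 803 ± 40.3. The intervals are also over genes, not fish. Fewer immune cells were therefore not excluded as the whole cause. Separate allele differences at each gene cannot be told apart from a shared fall: 100% of called members were lower, against 50.4% of other called genes, but that share is the pattern itself and decides nothing. The chrna3 genotype and any other difference shared by all fish of a genotype, such as infection or housing, cannot be told apart, since the lowest WT library lay 2.21 above the highest C246X library in mean log2 value.

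The genes near 0 in 1 genotype were weighed against reads moved between copies and against haplotypes. A copy of the same symbol called the other way was found for 2.38% of the 84 that changed and for 1.02% of other changed genes (odds ratio 2.38, 95% interval 0.276 to 9.31, two-sided Fisher's exact p = 0.216), which does not support moved reads as the whole cause, though copies under other symbols stay open. Haplotype blocks could not be told apart from scattered changes, since only 35.6% of these genes were placed: 64.9% of the 37 placed had a changed next neighbour, against 24.3% to 54.1% with permuted calls (permutation p = 0.000999, the smallest possible). Without neighbours of the same symbol stem the share was 54.1% (16.2% to 45.9% permuted), and for all changed genes, 66.5% of them placed, it was 43.7%, against a permuted interval ending at 42.0%, and without such neighbours 39.6% (35.8% to 39.7%). No biological explanation was tested for this pattern.

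Higher channel genes and lower ribosomal genes were weighed against gene span and cell mix. Across genes, which are not independent replicates, fold change rose with span (Spearman's rho 0.166), as it could with a difference in RNA quality that was not measured. The ribosomal median of −0.18 lay at the edge of span-matched lists (−0.18 to 0.0057, percentile 2.48 by current and older symbols, 3.51 by current symbols alone), so span could not be told apart there, nor for channels, where 68.2% of members had a span and their median of 0.35 (95% bootstrap interval 0.18 to 0.54) lay above matched lists (−0.026 to 0.24, percentile 99.96 and 99.93). The channel median lay 0.32 above that of neuron markers (95% bootstrap interval over genes 0.18 to 0.51), which an equal rise of all neuronal genes would not give. A change in the mix of neurons was not addressed, these lists were not matched on span, and the interval holds no spread between libraries. No biological explanation was tested for this pattern.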
